A study of Homo sapiens with 8 samples.

How the data were processed

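Chromatin immunoprecipitation of RNA polymerase II (Pol II) followed by sequencing was done on HEK-293T cells, a human embryonic kidney line that carries the SV40 large T antigen. Cells were left untreated or kept in 80 mM KCl for 1 h, a hyperosmotic stress. Each condition had 2 immunoprecipitated libraries, called replicates 1 and 2 after the numbers in their labels, and 2 input libraries, 8 samples in all. The input libraries entered only as the controls of the peak calls. The labels do not say whether replicates came from separate cultures. The p-values of comparisons between libraries therefore measure the spread between these libraries, which may be technical. The tests of gene lists, of neighbouring genes and of gene pairs run across genes, and their p-values do not measure that spread.

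Per the submitters' processing notes, reads were aligned to hg38, and the tools named there are Bowtie2 2.3.4.1, bedtools, edgeR, DESeq2, MACS2 2.1.1.20160309 and deepTools, with no role or order given. Per the file headers, MACS2 called peaks in each immunoprecipitated library on its own, against its own input, in paired-end mode with broad region calling and a q cutoff of 0.1 for broad regions, keeping 1 copy of each duplicate fragment and scaling the larger library towards the smaller. Peaks were thus called per library and not on pooled samples. Each deposited peak has a length in bp, a pileup signal (fragment coverage), a fold enrichment ratio over the input and a −log10 p-value and −log10 q-value, all as the authors' peak caller gave them. Of the column names, 2 had been lost in a spreadsheet and were taken, from their place and values, as the −log10 p and −log10 q columns. The fold enrichment and −log10 q of a peak are the authors' values and served only to describe, rank or filter peaks within their own list. Peaks had no summits, so the midpoint of a peak took the place of its summit.

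The gene values came from the authors' deposited table, which holds their own comparison of KCl with untreated cells for 21067 genes: a mean signal per gene, a log2 fold change with its standard error, a test score (the fold change divided by its standard error), a p-value and a Benjamini-Hochberg adjusted p-value. It was read as output of DESeq2, which the submitters' processing notes name and whose output has these columns. The name of the deposited table speaks of edgeR normalization by the authors before DESeq2. The kind of that normalization and the counted part of each gene are not given in the sources used here. Every mean signal in the authors' deposited table was a multiple of 0.25, within 1e-06, which is what the mean of whole numbers over 4 libraries gives when they are not scaled further. The authors' normalization could not be recomputed without values per library, so the counts of changed genes are also given with the fold changes centred. The adjusted p-values in the deposited table equalled Benjamini-Hochberg values recomputed over all genes to within 2e-07. No per-library gene values were used, so no gene test was refitted and the errors on gene values are the authors' standard errors. The table does not state its direction, which was settled from the peaks: the peak cover of genes, KCl minus untreated, rose with the authors' log2 fold change with a Spearman rho of 0.797 across 19995 genes, which are not independent replicates. Positive values were therefore read as higher in KCl. Names were matched to RefSeq symbols for 20038 of the genes, and 19995 had coordinates. For 25 names a spreadsheet had made dates, and these were not named.

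Gene positions came from the RefSeq gene table of GRCh38.p14, whose primary chromosomes have the coordinates of hg38. That table gives no strand. The design fixed before the data were examined had called for promoters and downstream regions of every protein-coding gene. Instead, the genome was divided without strand, in this order of priority, into gene ends (500 bp on either side of either end of a protein-coding gene), gene bodies, 10 kb flanks and elsewhere. For measurements past gene ends, the strand was taken from annotated divergent transcripts, the symbols of which add -DT to the symbol of the gene they start beside. A gene was oriented when its divergent transcript lay outside one of its ends by at most 5 kb, which oriented 562 of 19974 protein-coding genes.

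The comparisons covered chromosomes 1 to 22 and X. For each library, the share of peak-covered length was computed for each part of the genome. The downstream ratio was the covered share of the 10 kb past gene ends divided by the covered share of gene bodies, over oriented genes at least 2 kb long with a peak at the gene start in all 4 libraries and no other protein-coding gene in the window, 254 genes in all. A gene was counted as higher or lower when both KCl libraries lay above or below both untreated ones. Merged peak regions (overlap of 1 bp or more) were counted when both libraries of one condition and no library of the other had a peak, and the other 2 ways to split the 4 libraries into pairs served as a reference. Single values were compared by an exact 2-sided permutation test of 2 libraries against 2, which cannot give a p below 0.333, so none of these comparisons can pass a threshold of 0.05.

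Genes in the authors' deposited table were called changed at an adjusted p under 0.05. Of 21 gene lists fixed before the data were examined, the 20 with at least 5 measured members were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the authors' test score, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 20 lists. An estimated correlation needs values per library, so a preset correlation of 0.05 was the alternative. Named genes followed a rule fixed before the data were examined: the 10 largest rises and 10 largest falls among called genes with a mean signal at or above the median of 774.75, up to 4 members of each list with the smallest adjusted p, and for downstream windows the 5 genes with the largest rise and the 5 with the largest fall in covered length among genes whose libraries did not overlap, besides 3 published examples of downstream readthrough. Other genes are named below only as neighbours or list members, and were chosen after their values were seen. Some genes that the rule takes are not reported here.

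Depth was read from the file headers. After removal of duplicates the immunoprecipitated libraries held 32694065 to 42911082 fragments and the inputs 32644676 to 40786250. Peak lists carry no counting interval, so the spread between the 2 libraries is the only error given for peak measurements. Weak peaks depend on depth, since a deeper library lets a smaller enrichment pass the same q cutoff.

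Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. The steps were tested on simulated data. Covered bases differed from a base-by-base count in 0 of 500 windows, and all of the 300 regions planted in KCl libraries and the 200 planted in untreated libraries were found. With the real standard errors of the 21067 genes and 200 genes changed in a simulated comparison of KCl with untreated cells, centred calls found 69 of 100 genes changed by 1 on the log2 scale and 100 of 100 changed by 2, with 7 false calls among 176. After a shift of every gene, with genes and noise drawn anew, 55 of 100 and 96 of 100 were found. The 200 genes rose and fell in equal numbers, whereas in the data 8464 genes were lower and 2642 higher. Centring on the median under such an imbalance was therefore not tested. Both shifted gene sets and 0 of 18 unshifted sets were called by cameraPR over the same 21067 genes. Their scores were drawn without correlation between genes, so the preset correlation was not tested. Alternatives covered stricter peak lists (−log10 q of at least 5, or fold enrichment of at least 4), equal numbers of peaks, other windows, leaving out each library, other thresholds and other centrings of the fold changes. Peaks on contigs outside chromosomes 1 to 22 and X were not used in the comparisons.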

Results

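Pol II occupancy was profiled by chromatin immunoprecipitation and sequencing in HEK-293T cells, untreated or after 1 h in 80 mM KCl, with 2 libraries per condition. The comparison asks where on the genome Pol II lies when cells face hyperosmotic stress. Untreated replicates 1 and 2 held 37946068 and 39452498 fragments after removal of duplicates, and KCl replicates 1 and 2 held 32694065 and 42911082. The share of redundant fragments was 0.20 and 0.21 in the untreated libraries and 0.26 and 0.17 in the KCl libraries. The deepest and the shallowest library were thus both from KCl-treated cells.

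The number of Pol II peaks differed by less than the spread between replicates, but their positions differed between the conditions. Untreated libraries had 105260 and 103627 peaks and KCl libraries 102877 and 106865, a difference in means of 427.5 against SDs of 1155 and 2820 (n = 2 each, exact 2-sided permutation p = 1). Without KCl replicate 2 the difference was -1566.5, and without untreated replicate 2 it was -389. The covered length was 222 Mb ± 13.3 (SD, n = 2) in untreated cells and 230 Mb ± 36.6 (SD, n = 2) in KCl. Of the bases covered in either of 2 libraries, the untreated replicates shared 67.8% and the KCl replicates 62.7%, whereas an untreated and a KCl library shared 29.9% to 34.7%. Merging the 4 lists gave 180412 regions, of which 18299 had a peak in every library. Peaks with a −log10 q of at least 5 were fewer in KCl, at 10244 and 9818 against 14599 and 14219 in the untreated libraries.

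After KCl, Pol II peaks lay less on genes and more on the sequence between them. Gene bodies took 74.2% ± 0.337 (SD, n = 2) of the covered length in untreated cells and 63.1% ± 1.77 (SD, n = 2) in KCl. Sequence more than 10 kb from any protein-coding gene took 4.51% ± 0.0657 (SD, n = 2) in untreated cells and 14.8% ± 1.09 (SD, n = 2) in KCl. The 10 kb flanks of genes took 13.2% ± 0.0895 in untreated cells and 15.4% ± 0.244 in KCl, and gene ends took 8.13% ± 0.313 and 6.73% ± 0.433 (SD, n = 2 each). All 4 differences exceeded the spread between replicates, each with both KCl libraries on one side of both untreated libraries, and gave an exact permutation p of 0.333, the smallest that 2 against 2 libraries allow. With a −log10 q of at least 5 the difference, KCl minus untreated, was 4.62 percentage points elsewhere and -5.88 in gene bodies, and with a fold enrichment of at least 4 it was 4.27 and -5.57, against 10.3 and -11.1 with all peaks. Counting peaks by midpoint turned the direction for gene ends, to 5.85% ± 0.193 in untreated cells and 6.68% ± 0.729 in KCl (SD, n = 2 each).

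**Figure D1:**
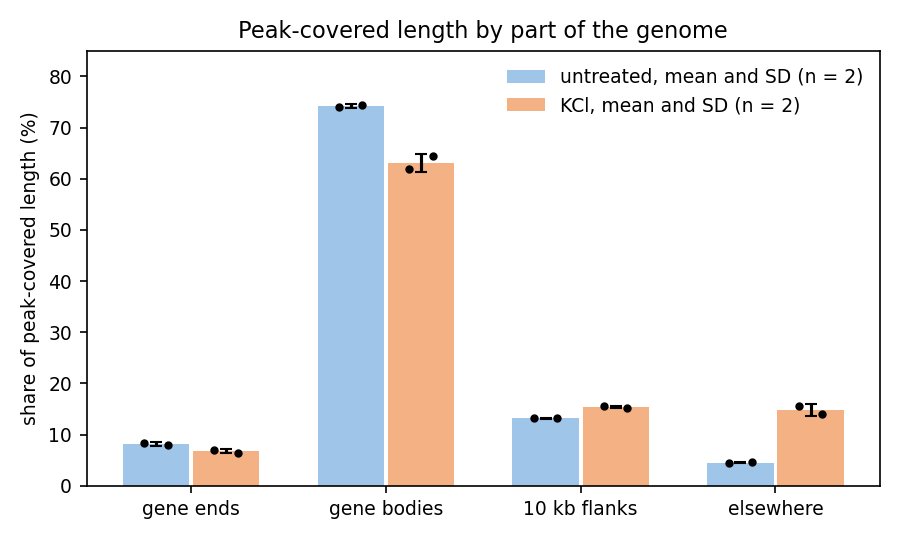
Share of the peak-covered length of each library (%, vertical axis) on gene ends, gene bodies, 10 kb flanks and elsewhere; bars give the mean of 2 libraries, whiskers the SD and points the libraries. The share elsewhere was 4.51% in untreated cells and 14.8% in KCl, and that of gene bodies was 74.2% and 63.1%.

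A larger part of the covered length lay in long peaks after KCl, although the typical peak was not longer. The median peak length was 589 and 652 bp in the untreated libraries and 570 and 607 bp in the KCl libraries. Peaks of 20 kb or more, a measure added after the lists had been seen, held 28.6% ± 1.81 (SD, n = 2) of the covered length in untreated cells and 41.2% ± 4.79 (SD, n = 2) in KCl, with an exact permutation p of 0.333. The number of such peaks overlapped between the conditions, at 1616 and 1870 in the untreated libraries and 1784 and 2446 in KCl (exact permutation p = 0.667). The longest peaks of the untreated libraries spanned 158619 and 157499 bp and those of the KCl libraries 247073 and 282327 bp.

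Regions found in one condition only were many in both directions and lay on different parts of the genome. Both KCl libraries and no untreated library had a peak in 17557 regions, with a median of 1319 bp, and 37.3% of their length lay more than 10 kb from any protein-coding gene. Both untreated libraries and no KCl library had a peak in 21663 regions, with a median of 1163 bp, of which 81.5% of the length lay in gene bodies and 5.39% elsewhere. The 2 directions came to 39220 regions, against 2430 and 2195 for the other 2 splits of the 4 libraries. Most were weak peaks: with a −log10 q of at least 5, 228 regions were found in KCl only and 3276 in untreated cells only. With 1 library standing for its condition the counts grew, to 52003 and 41149 in KCl only without KCl replicate 1 or 2, and to 49242 and 44971 in untreated cells only without untreated replicate 1 or 2.

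Past the ends of genes, peak cover in untreated cells fell off within about 10 kb, whereas in KCl it stayed level as far as 20 kb. In 196 oriented genes with 20 kb free of other protein-coding genes, the first 2 kb past the gene end were covered to 45.4% ± 1.10 (SD, n = 2) in untreated cells and 27.8% ± 6.06 (SD, n = 2) in KCl. Between 15 and 20 kb past the gene end, cover was 4.47% ± 0.162 (SD, n = 2) in untreated cells and 32.1% ± 4.42 (SD, n = 2) in KCl, a value from a window chosen after the profile had been seen. In the first kb after the gene start, cover was 94.0% and 94.8% in the untreated libraries and 73.1% and 82.9% in the KCl libraries. The difference at 15 to 20 kb shrank with stricter peaks, to 11.3% in KCl against 2.88% in untreated cells with a −log10 q of at least 5.

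**Figure D2:**
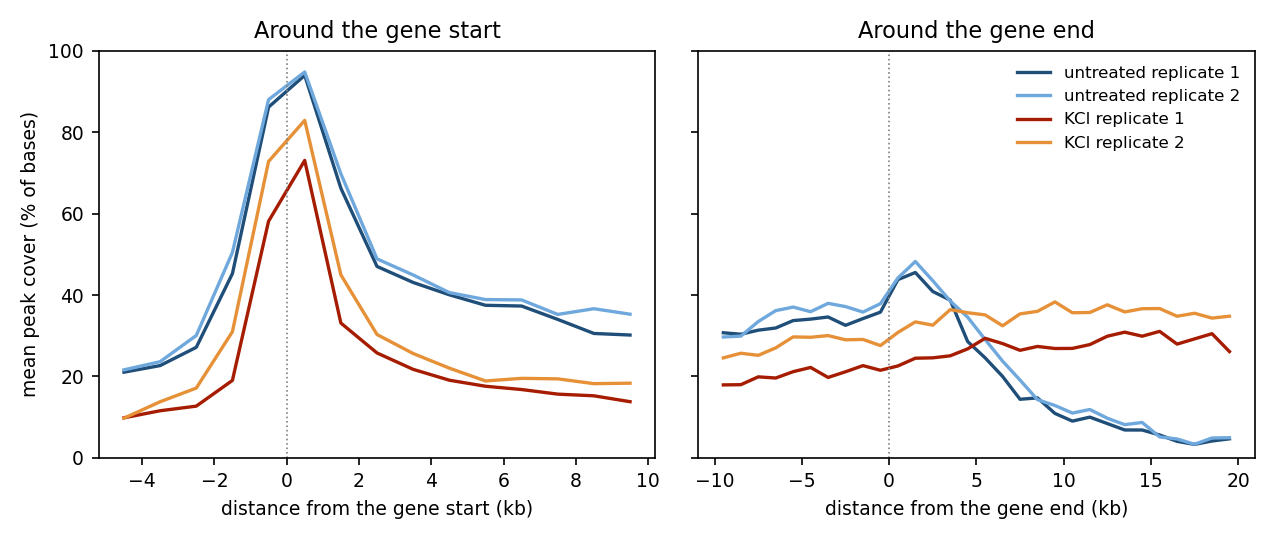
Mean peak cover (% of bases in 1 kb bins, vertical axis) around the start and the end of 196 oriented protein-coding genes (distance in kb, horizontal axis), 1 line per library. Beyond 15 kb past the gene end, the untreated libraries lie near 4.47% and the KCl libraries near 32.1%, while at the gene start the KCl libraries lie below the untreated ones.

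The ratio of downstream to gene body cover, the measure fixed in advance, was 2.16 and 2.08 in the untreated libraries and 3.03 and 2.65 in the KCl libraries. The mean was 2.12 ± 0.0573 (SD, n = 2) in untreated cells and 2.84 ± 0.268 (SD, n = 2) in KCl, a difference of 0.42 on the log2 scale over 254 genes (exact permutation p = 0.333). Gene bodies were covered to 15.1% ± 1.27 in untreated cells and 11.6% ± 3.25 in KCl (SD, n = 2 each). The 10 kb past the ends were covered to 32.0% ± 1.82 and 32.5% ± 6.11 (SD, n = 2 each). The KCl libraries differed in where the change lay. Gene bodies were covered to 9.30% in KCl replicate 1 and 13.9% in replicate 2, against 14.2% and 16.0% in the untreated libraries. The 10 kb past the ends were covered to 28.1% and 36.8%, against 30.7% and 33.2% in the untreated libraries. The change in the ratio depended on the window, which also changes the set of genes. With 5 kb, over 302 genes, the ratio was 2.88 ± 0.146 in untreated cells and lower, 2.63 ± 0.150, in KCl. With 20 kb, over 196 genes, it was 1.39 ± 0.0221 and higher, 2.96 ± 0.304, in KCl (SD, n = 2 each).

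Single genes went both ways. Downstream cover in both KCl libraries exceeded that in both untreated libraries at 76 of the 254 genes and lay below it at 89. The balance turned with the window, which also changes the set of genes. With 5 kb, 52 of 302 genes were higher and 108 lower, and with 20 kb, 86 of 196 were higher and 52 lower. With 10 kb, the other 2 splits of the libraries gave 20 and 1 genes, and 1 and 13. Chance gives such an order, in either direction, to a share of 0.333 of untied genes. Gene body cover was higher at 46 of the 254 genes and lower at 142. The largest gains were past MICB, a stress-induced ligand of natural killer cell receptors, PHLDA1, KLF2, a Krüppel-like transcription factor, DNAJB5, a heat shock protein of the HSP40 family, and NUP93, a nuclear pore protein. The KCl peaks over KLF2 and its window, of 33.5 and 46.5 kb, also reached EPS15L1, so that gain cannot be assigned to KLF2 alone. Whether peaks at the other genes reached a neighbour was not examined. Past MICB (chromosome 6, 31494918 to 31511124, hg38) and PHLDA1 (chromosome 12, 76025447 to 76031776), peaks covered 0 kb of the 10 kb in either untreated library and 10 kb in both KCl libraries. Past NUP93 (chromosome 16, 56730129 to 56850286) peaks covered 7.68 and 10 kb in KCl and none of the window in untreated cells, while cover of the gene body was 2.93% and 9.8% in KCl and 31.9% and 44.3% in untreated cells. The largest losses were past RPAP3, SEC61G, ZNF691, MRPS30 and COPS8. Past COPS8, which encodes a subunit of the COP9 signalosome (chromosome 2, 237085889 to 237100474), peaks covered 8.36 and 8.72 kb in untreated cells and 0 kb in KCl, and the gene body of COPS8 had no peak in either KCl library. Of the published examples of downstream readthrough, OSGIN2 and CXXC4 had log2 fold changes of -1.53 and -1.73 in the authors' deposited table, both past the threshold, and none of the 3 was among the oriented genes.

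Over whole genes, Pol II occupancy fell far more often than it rose. In the authors' deposited table, 8464 of 21067 genes were lower in KCl, 2642 were higher and 9961 did not pass an adjusted p of 0.05 (authors' DESeq2 values). By at least 1 on the log2 scale, 5421 genes fell and 1544 rose in the authors' deposited table, and the median log2 fold change over all genes was -0.28. Genes without a peak in any library, 3789 in all, had a median of -0.04 in the authors' deposited table, with quartiles of -0.17 and 0.11. The name of the deposited table speaks of edgeR normalization by the authors, of a kind not given in the sources used here, so its centring could not be checked from the table alone. Centred on the median of all genes, 6518 genes of the authors' deposited table were lower and 3779 higher, so that 36.7% of the called genes were higher in place of 23.8%. Peaks covered the fallen genes to 49.8% and 52.7% in the untreated libraries and 21.5% and 28.8% in the KCl libraries. The risen genes were covered to 24.8% and 26.1% in untreated cells and 57.9% and 61.1% in KCl. The cover comes from the same libraries as the fold changes and also set the direction of the deposited table. Its order, here and at the single genes named below, is therefore no separate evidence for the rises and falls.

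Among genes at or above the median signal, the 10 with the largest rises each lay next to another gene within one long KCl peak. In the authors' deposited table they were AZU1, an antimicrobial protein of neutrophil granules, NMRK2, a nicotinamide riboside kinase of muscle, TRIM72, a membrane repair protein of muscle, FGF18, a growth factor, LILRA6, a leukocyte receptor, SLC5A5, the sodium iodide symporter of the thyroid, CD79A, a part of the B-cell receptor, CPNE7, LRCOL1 and PERM1, a regulator of muscle metabolism. AZU1 (chromosome 19, 827837 to 832018) had a log2 fold change of 6.50 (SE 0.28, adjusted p = 1.9e-115) in the authors' deposited table, and FGF18 (chromosome 5, 171419647 to 171457626) one of 5.08 (SE 0.195, adjusted p = 2.48e-145). For the other 8 the log2 fold changes in the authors' deposited table ran from 4.64 for PERM1 to 6.07 for NMRK2. Peaks covered each of the 10 genes to 100% in both KCl libraries and to between 0% and 11.6% in the untreated libraries. FGF18 lay in KCl peaks of 86.8 and 86.1 kb that also held NPM1 and NMRK2 in peaks of 66.2 and 66 kb that reached EEF2. CPNE7 shared its KCl peaks of 40.6 and 42.1 kb with RPL13 and SPG7, and LILRA6 its peaks of 57.9 and 60.8 kb with RPS9. Of these neighbours, NPM1 rose less, by 0.60, EEF2 by 0.74 and RPS9 by 0.56 on the log2 scale in the authors' deposited table. RPL13 did not pass, at 0.19 (adjusted p = 0.535). These were chosen neighbours, and SPG7 and the remaining genes in the same peaks were not looked up.

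**Figure D3:**
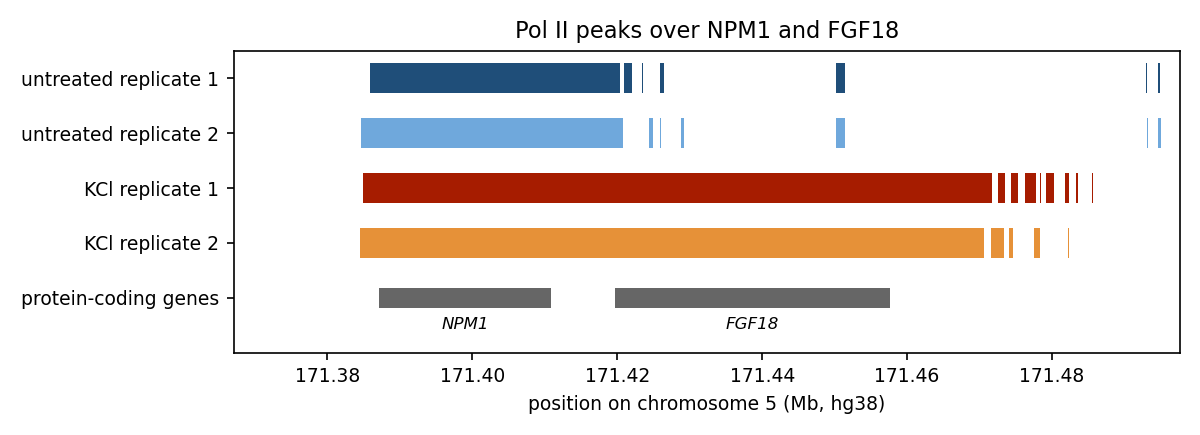
Peaks of the 4 libraries (1 row each) and protein-coding genes (bottom row) on chromosome 5 around NPM1 and FGF18, position in Mb on the horizontal axis. In the untreated libraries the long peak ends just inside FGF18, at 171420368 and 171420787, and in the KCl libraries it runs on to 171471764 and 171470583.

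Some of the risen genes shared a KCl peak with a neighbour. Of the 2159 protein-coding genes that were higher in the authors' deposited table, 27% lay whole within a peak shared with another protein-coding gene in both KCl libraries, and 8.52% did so in both untreated libraries. That order follows in part from the choice of genes by their rise, since genes that gain Pol II also gain peak cover. Among the 7298 protein-coding genes that did not pass the threshold in the authors' deposited table, the shares were 10.8% in KCl and 8.51% in untreated cells. Among the 7106 that were lower the order was the opposite, 5.74% in KCl and 14% in untreated cells. The share of risen genes was largest on chromosome 19, at 20.1% of its 1246 measured protein-coding genes, and smallest on chromosome 18, at 5.98% of 234. By length, 19.4% of protein-coding genes of up to 5 kb rose against 7.18% of those over 100 kb, per the authors' deposited table, and 44.4% and 23.5% fell, so that the longest genes were called less often in both directions.

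Peak cover was lower in both KCl libraries than in both untreated libraries at 8 of the 10 genes with the largest falls. These falls were ranked only among genes at or above the median signal. In the authors' deposited table GSTO1, a glutathione transferase (chromosome 10, 104254173 to 104267455), had a log2 fold change of -3.26 (SE 0.233, adjusted p = 4.82e-42), and its peak cover was 100% in both untreated libraries against 2.88% and 3.12% in KCl. HPS1, a subunit of a lysosomal trafficking complex, stood at -3.05 and TMBIM4 at -2.99 in the authors' deposited table, with cover of 63.1% and 76.7% of HPS1 in untreated cells and 1.73% and 2.32% in KCl. RNU5D-1, a U5 small nuclear RNA gene, and SLFNL1 stood at -3.14 and -2.86 in the authors' deposited table and were covered to 100% in every library. TAMM41, at -2.85 in the authors' deposited table, was covered to 43.1% and 45.5% in untreated cells and still to 21.8% and 28.5% in KCl. ZSCAN16-AS1, C3orf17, TOP3B and FAM217B completed the list in the authors' deposited table, with values from -2.96 to -2.79. ZSCAN16-AS1 is named as an antisense gene. Immunoprecipitated DNA does not carry the strand of the transcript, so its value cannot be told from that of an overlapping gene.

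Immediate early genes, the transcription factors and regulators that respond first to many stimuli, rose as a group. Of 35 measured members, 21 were higher and 4 lower in the authors' deposited table, the same counts when adjusted over the list alone, and the list ranked above the other genes (cameraPR adjusted p = 6.16e-09). In the authors' deposited table EGR1, a zinc finger transcription factor, rose by 2.39 (SE 0.209, adjusted p = 2.78e-28), GADD45B, a stress sensor, by 2.22 (SE 0.205), ZFP36, a factor of mRNA decay, by 2.42 (SE 0.225) and ARC, a regulator of synapses, by 2.46 (SE 0.233). Of the 21 risen members, 7 lay in a peak shared with another protein-coding gene in both KCl libraries and 4 did so in both untreated libraries. ZFP36 was one, in KCl peaks of 55.5 and 56.5 kb that also held 5 other protein-coding genes, whereas GADD45B stood alone in KCl peaks of 7.78 and 8.54 kb. The 4 that fell in the authors' deposited table were EGR2, SRF, FOSL2 and KLF6.

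Genes of other tissues, a list fixed as a background because a kidney line should not use them, also ranked above the other genes (cameraPR adjusted p = 1.44e-05). Of 16 measured members, 6 were higher and 2 lower in the authors' deposited table, the same adjusted over the list alone. Besides CD79A, these included the alpha globins HBA2 at 2.72 and HBA1 at 2.15 in the authors' deposited table. HBA1 and HBA2 are near-identical copies, so reads may have been split between them. Both lay in the same KCl peaks, of 21.8 and 22.1 kb, shared with the other alpha-like globins HBM and HBQ1, so their rises may not be separate. Peaks in the untreated libraries already covered HBA1 to 100% in both and HBA2 to 55.4% and 59.4%.

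Genes of oxidative phosphorylation fell together. Of 71 measured members, 54 were lower and 2 higher in the authors' deposited table, and 55 were lower and 2 higher when adjusted over the list alone (cameraPR adjusted p = 9.28e-06). In the authors' deposited table NDUFB8, NDUFV2 and NDUFA9, parts of complex I, stood at -2.82 (SE 0.249), -2.48 (SE 0.233) and -2.44 (SE 0.243), and ATP5G2, a part of the ATP synthase, at -2.44 (SE 0.253). Cover of NDUFB8 was 100% in both untreated libraries and 5.5% and 6.8% in KCl. Genes of C2H2 zinc finger proteins, the largest family of human transcription factors, fell likewise, with 351 lower and 19 higher of 505 measured in the authors' deposited table and 352 and 21 adjusted over the list alone (cameraPR adjusted p = 6.6e-08). ZNF197 at -2.71 (SE 0.246) and ZNF594 at -2.54 (SE 0.228) were examples in the authors' deposited table, besides ZNF397 and the pseudogene ZNF271P. As members of one family, they share similar sequence, and the authors' handling of reads that fit several genes is not given in the sources used here.

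Genes of the machinery that ends transcription fell as well, with a weaker test. Among factors of cleavage, polyadenylation and termination, 13 of 20 were lower and none higher in the authors' deposited table, and 15 were lower when adjusted over the list alone (cameraPR adjusted p = 0.0304). With a preset correlation of 0.05 the adjusted p was 0.141, and with members at or above the median signal it was 0.384. In the authors' deposited table CSTF2 stood at -2.42 (SE 0.238), FIP1L1 at -2.07 (SE 0.233), CSTF2T at -1.78 (SE 0.234) and CPSF2 at -1.66 (SE 0.238), all of them parts of the machinery that cuts and polyadenylates the 3' ends of mRNA. The median of that list was -1.01 in the authors' deposited table, against -0.28 for all genes.

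Ribosomal protein genes ranked above the other genes, although most of them did not pass the threshold themselves. Of 75 measured members, 21 were higher, 12 lower and 42 not past the threshold in the authors' deposited table, with 20 higher and 12 lower adjusted over the list alone. Their median log2 fold change was 0.10 in the authors' deposited table (cameraPR adjusted p = 0.00343), and the call was lost with a preset correlation of 0.05 (adjusted p = 0.141). FAU rose by 2.19 (SE 0.211) in the authors' deposited table. The other members with the smallest adjusted p in the authors' deposited table were paralogues outside the standard set of the ribosome, RPL39L at -2.37, RPS27L at -2.19 and the muscle paralogue RPL3L at 1.57. Centring on the median of all genes moves every value up by 0.28 and leaves these directions in place.

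**Figure D4:**
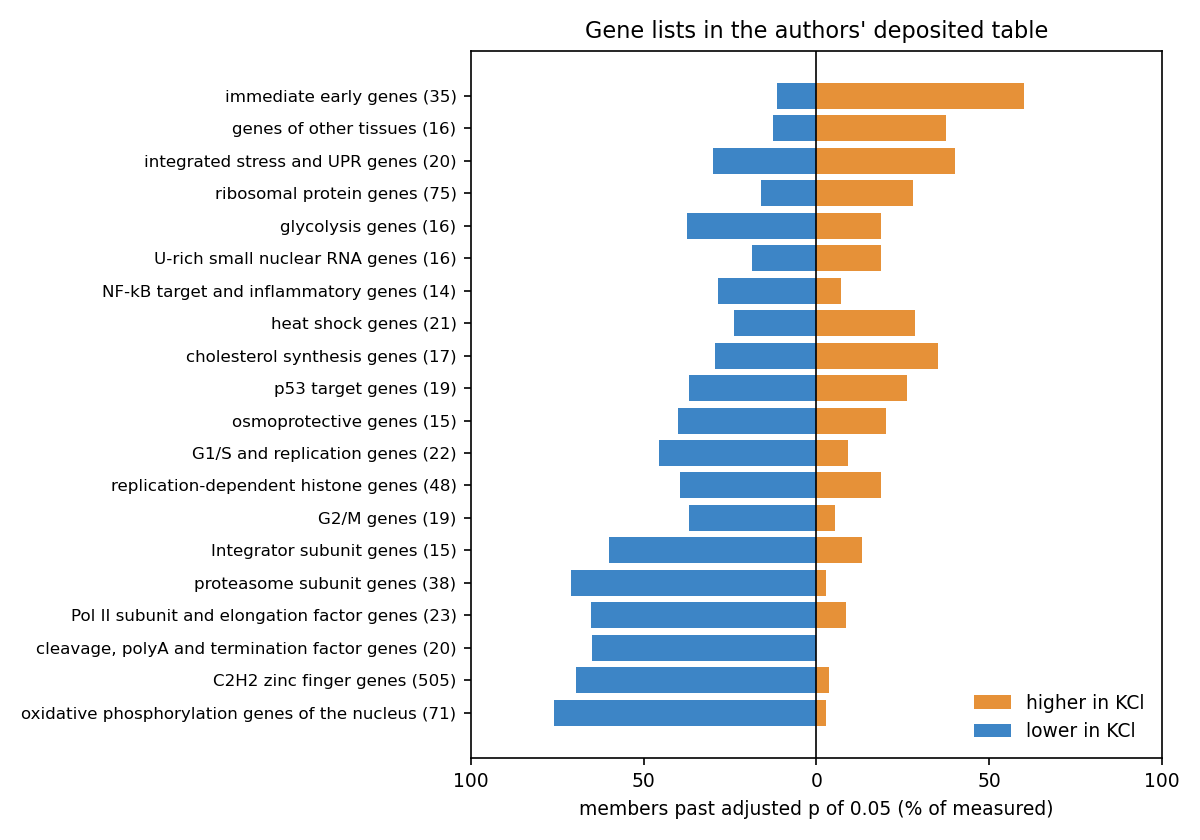
Measured members of each of the 20 tested gene lists (number in brackets) that were higher (right) or lower (left) in KCl at an adjusted p of 0.05 in the authors' deposited table, as % of the measured members. Immediate early genes stand at the top, with 21 of 35 higher, and oxidative phosphorylation genes at the bottom, with 54 of 71 lower.

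The other 14 tested lists did not pass the threshold against the other genes, and most held members that went both ways. Of 15 osmoprotective genes, which hold NFAT5, the transcription factor of the osmotic response, its known targets and transporters of osmolytes and ions, 3 were higher and 6 lower in the authors' deposited table, the same adjusted over the list alone (cameraPR adjusted p = 0.546). The risen ones in the authors' deposited table were all transporters: SLC6A12 of betaine at 1.48 (SE 0.237), SLC38A2 of neutral amino acids at 1.21 (SE 0.205) and SLC6A6 of taurine at 1.04 (SE 0.213). S100A4 fell, at -1.73 (SE 0.382) in the authors' deposited table. Among 21 heat shock genes 6 were higher and 5 lower in the authors' deposited table, the same adjusted over the list alone (adjusted p = 0.308 by cameraPR), with the collagen chaperone SERPINH1 at -2.52 and the heat shock factor HSF2 at -1.26. Of 20 genes of the integrated stress and unfolded protein responses, 8 were higher and 6 lower in the authors' deposited table, 8 and 7 adjusted over the list alone (adjusted p = 0.308 by cameraPR). In that list of the authors' deposited table DDIT4, an inhibitor of mTORC1 signalling, stood at 1.58, while PHGDH of serine synthesis and ASNS, asparagine synthetase, stood at -2.05 and -1.68.

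Among 19 p53 targets, 5 were higher and 7 lower in the authors' deposited table, the same adjusted over the list alone (adjusted p = 0.739 by cameraPR), with the cell death gene BBC3 at 1.86 and PHLDA3 at -2.68. Of 14 NF-kB target and inflammatory genes 1 was higher and 4 lower in the authors' deposited table, the same adjusted over the list alone (adjusted p = 0.825 by cameraPR), with TNFAIP3 at -1.64 and CXCL3 at -2.28. Cholesterol synthesis genes split into 6 higher and 5 lower of 17 in the authors' deposited table, unchanged when adjusted over the list alone (adjusted p = 0.0982 by cameraPR), with IDI1 at 1.72 and MVK at -1.27. Of 16 glycolysis genes 3 were higher and 6 lower in the authors' deposited table, 4 and 6 adjusted over the list alone (adjusted p = 0.474 by cameraPR), with TPI1 at 1.54 and LDHB at -1.82.

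The remaining lists did not pass the threshold against the other genes either; of all 21067 genes, 40.2% were lower in the authors' deposited table. Proteasome subunits had 27 lower and 1 higher of 38 in the authors' deposited table, the same adjusted over the list alone (adjusted p = 0.0586 by cameraPR), with PSMD13 at -1.83 and PSMB6 at -1.87. Of 23 Pol II subunit and elongation factor genes 15 were lower and 2 higher in the authors' deposited table, 15 and 3 adjusted over the list alone (adjusted p = 0.198 by cameraPR), with SSRP1 at -1.97 and POLR2C at -1.58. Of 15 Integrator subunits, parts of a complex that cuts nascent RNA, 9 were lower and 2 higher in the authors' deposited table, the same adjusted over the list alone (adjusted p = 0.358 by cameraPR), with INTS12 at -2.01 and INTS10 at -1.88. Of 22 G1/S and replication genes 10 were lower and 2 higher, and of 19 G2/M genes 7 were lower and 1 higher in the authors' deposited table, the same adjusted over the list alone (adjusted p = 0.739 and 0.825 by cameraPR). CENPF fell, at -1.47 in the authors' deposited table, while the mitotic kinase AURKB rose by 1.30. Histone genes that depend on replication had 19 lower and 9 higher of 48 in the authors' deposited table, the same adjusted over the list alone (adjusted p = 0.905 by cameraPR). The linker histone genes HIST1H1D and HIST1H1C stood at -3.89 (SE 0.311) and -2.43 (SE 0.203) in the authors' deposited table. The core histone genes have near-identical copies, so HIST1H4H at -2.60 and HIST1H4E at -2.39 in the authors' deposited table are uncertain. Small nuclear RNA genes had 3 higher and 3 lower of 16 in the authors' deposited table, the same adjusted over the list alone (adjusted p = 0.474 by cameraPR). The list pools different kinds of small nuclear RNA gene, so this split does not describe 1 kind. Among the named members, RNU6-1 of U6 and RNU6ATAC of U6atac stood at 2.46 and 1.63 in the authors' deposited table. The U5 genes RNU5D-1 and RNU5F-1 stood at -3.14 and -1.29. Many copies of such genes make single values uncertain. The mean signals of RNU6-1 and RNU6ATAC were 138.5 and 65.5, well below the median of 774.75. In 8 of the 20 lists, none of them past the threshold, the median, the mean and the test differed in sign: the osmoprotective, heat shock, stress response, NF-kB, p53, glycolysis, cholesterol and small nuclear RNA genes.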

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

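The tests named in this part for the number of falls were chosen after the results they measure had been seen. The tests before gene starts and with no gene of any type in the window were set beforehand.

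Peaks also lay on contigs outside the assembled chromosomes, which no comparison above uses: 165 and 171 in untreated replicates 1 and 2, and 184 and 217 in KCl replicates 1 and 2.

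Far more genes fell than rose in the authors' deposited table, 8464 against 2642. A scaling or a lower depth that alone lowers every gene in KCl would lower genes without peaks as well. Their median log2 fold change was -0.0447, against -0.28 for all genes. This cannot exclude a scaling together with weaker enrichment, which leaves a larger share of fragments outside peaks. Weaker enrichment in the KCl libraries stays open: of the 4384 genes covered to 80% or more in both untreated libraries, 59.4% were lower and 8.80% higher, against 40.2% and 12.5% of all genes. A loss of Pol II from many genes in stressed cells would lower these genes too, so the 2 may act together and cannot be told apart without a reference added to each library.

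Peak cover 15 to 20 kb past gene ends was higher by 27.6 percentage points in KCl. Longer peaks on every side of genes, or more peaks everywhere between genes, would raise the cover before gene starts too, but there the rise at 15 to 20 kb was 0.0814 of that past gene ends, 6.85% ± 1.02 against 4.60% ± 0.429 (SD, n = 2 each, 320 genes). Neighbouring genes that are not protein-coding do not account for it, since in 110 genes with no annotated gene of any type in the window the rise was 1.15 times as large. The pattern may therefore reflect Pol II that runs on past gene ends under hyperosmotic stress, a hypothesis found and tested on the same 4 libraries, with no RNA measured here.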

How the results depend on the processing

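Alternatives centred on genes without peaks, those for long peaks, those for the window 15 to 20 kb past gene ends and the measurement on both flanks were chosen after seeing the data; the others were fixed before. No alternative that needs gene values per library was run: refits with edgeR, DESeq2 or limma, another filter or pseudocount, the replicate block on genes, genes without each library and an estimated correlation of gene lists. Of 383 alternative values for 136 results, 355 kept their direction and their side of the threshold or stayed within 1.5 times the count. Of the 355, 200 were centred values of named genes, most of them picked for large changes or small adjusted p. The centring could hardly turn their calls, so these 200 are a weak check. Adjusted p-values recomputed over all genes repeat the deposited ones and are no check. The cause was not tested for any of the following, beyond the fewer genes, peaks or libraries that a setting leaves.

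Genes higher and lower numbered 1544 and 5421 with an absolute log2 fold change of at least 1, and 1321 and 5024 when only genes at or above the median signal were tested. Centred on genes without a peak they numbered 2782 and 8155. All 200 centred values of named genes kept their call and direction. Gene lists kept their calls except ribosomal protein genes (adjusted p = 0.141) and cleavage factors (0.141) with a preset correlation of 0.05, and with members at or above the median signal cleavage factors (0.384), lost, and cholesterol synthesis genes (0.047), gained. Without passing the threshold, the direction turned for NF-kB targets when genes were ranked by log2 fold change (adjusted p = 0.963), and for histone genes (0.48) and G2/M genes (0.979) with members at or above the median signal. Genes of other tissues had 1 member at or above the median signal, under the minimum of 5, so that setting is no check of their call.

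The difference in the number of peaks, KCl minus untreated, turned to -4378 with a −log10 q of at least 5 and to -4244 with a fold enrichment of at least 4, and without single libraries ran from -1566.5 (without KCl replicate 2) to 2421.5 (without KCl replicate 1); without untreated replicate 2 it was -389. With the stricter lists the share elsewhere differed by 4.62 and 4.27 percentage points and that of gene bodies by -5.88 and -5.57. By midpoint the share on gene ends rose by 0.836 percentage points. Regions of KCl only numbered 228 and those of untreated only 3276 with a −log10 q of at least 5, and 198 and 3112 with a fold enrichment of at least 4. Without single libraries they ran from 18913 to 52003 (without KCl replicate 1; 41149 without KCl replicate 2) and from 22935 to 49242 (without untreated replicate 1; 44971 without untreated replicate 2), since 1 library then stands for a condition.

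The log2 difference in the downstream ratio was -0.13 with 5 kb, 1.09 with 20 kb, 0.55 over both flanks of 3113 genes, 0.69 and 0.78 with the stricter lists, and 0.32 to 0.51 without single libraries. Genes with more and less downstream cover numbered 22 and 28 with a −log10 q of at least 5, and 52 had less with 20 kb. At 15 to 20 kb past gene ends the difference was 8.45 and 7.71 percentage points with the stricter lists and 24.5 to 30.7 without single libraries. The share in peaks of 20 kb or more differed by 9.21 to 16.0 points without single libraries and by 22.8 and 23.2 with the stricter lists.

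Libraries with the same replicate number did not deviate together (r = -0.0187 over 71487 regions). With only 2 pairs, this cannot show whether they shared a culture or a batch. Both replicates 2 and neither replicate 1 had a peak in 1885 regions, against 545 the other way. With the replicate block the log2 difference in the downstream ratio was 0.42, and 85 genes had more and 90 less downstream cover in both pairs. KCl replicate 1, the shallowest library, had the lowest covered length, 204 Mb, and KCl replicate 2, the deepest, the highest, 256 Mb; how far depth sets the number of weak peaks was not tested.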

Other observations

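The tests of the neighbours of oriented genes, of gene pairs and of overlapping genes were set before their results were seen. The cover up to 100 kb and the strongest peaks were looked at after the profile and the peak lists had been seen.

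The cover past gene ends reached far in KCl. In 82 oriented genes with 100 kb free of other protein-coding genes, sequence 20 to 30 kb past the gene end was covered to 29.2% ± 2.23 in KCl and 2.94% ± 0.211 in untreated cells (SD, n = 2 each). At 40 to 50 kb the values were 21% ± 0.455 and 2.19% ± 0.129, at 60 to 70 kb 10.9% ± 0.0470 and 1.99% ± 0.186, and at 90 to 100 kb 4.77% ± 0.525 and 1.39% ± 0.152 (SD, n = 2 each). All 4 differences exceeded the replicate spread, with an exact permutation p of 0.333, the smallest possible. In the first 5 kb the order was the opposite, 22.7% ± 5.23 in KCl and 38.1% ± 1.34 in untreated cells.

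The strongest peaks of every library lay on small RNA genes. Among the 20 peaks with the highest fold enrichment by the authors' peak caller, 18 and 17 in the untreated libraries and 19 in each KCl library overlapped genes of small nuclear RNAs or of the U3 small nucleolar RNA. The strongest peak of KCl replicate 1, on chromosome 17 from 19060752 to 19065223, had a fold enrichment of 531 within its own list.

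The long KCl peaks that join the 10 genes with the largest rises to their neighbours raise the hypothesis that some genes gain Pol II because they lie past the end of another transcribed gene, which predicts more rises past gene ends than before gene starts. Among the nearest protein-coding neighbours within 20 kb, 50 of 212 past the end were higher in the authors' deposited table (23.6%, exact 95% interval 18% to 29.9%). Before the start, 14 of 131 were higher (10.7%, 5.97% to 17.3%), an odds ratio of 2.58 (2-sided Fisher's exact p = 0.00271). On both sides more neighbours were lower than higher, 89 past the end (42.0%) and 73 before the start (55.7%). In 28 pairs of genes joined by an annotated readthrough transcript, the second gene had the higher log2 fold change in 18 (2-sided exact sign test p = 0.185); the bound set for this test was wrong, since with so few pairs a p that misses the threshold does not show that the genes did not differ. Protein-coding genes that overlap no annotated gene were higher 1.27 times as often as those that do, 14.8% of 7319 against 11.6% of 9244. Reads shared with an overlapping annotated gene thus cannot account for the 1083 risen genes without an overlap. For the 1076 risen genes with one, the comparison cannot decide, since the 2 groups were not matched for gene length. Position past a neighbour's end may thus account for part of the rises, but the orientation of the neighbours themselves was not known. Whether it plays a part at risen genes that stood alone in their peaks, such as GADD45B, was not tested. Standing alone does not settle it, since EGR1 shared a peak of 113 kb with ETF1 and HSPA9 in KCl replicate 1. In KCl replicate 2, EGR1 stood alone in a peak of 20.2 kb.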
